A study of Mus musculus with 46 samples.

How the data were processed

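Gene expression was measured in mouse lung of wild type and Nrf2 mutant animals at 0 h and after 24, 48 and 72 h in 100% oxygen, on 3 types of oligonucleotide array called A, B and C here. The 46 arrays fell into 8 groups of 1 genotype and 1 time. The labels give replicates 1a and 1b in each group. On array type A, replicate 1a was missing for the mutant at 0 h and for wild type at 24 h, so 14 arrays of type A and 16 each of types B and C were used. The labels do not say whether 1a and 1b are separate animals, so each p-value measures only the spread between these samples.

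The deposited values are linear intensity values, 1 per probe set and array. The tool and the genome build that the authors used are not given in the sources used here. The 2%-trimmed mean of the deposited intensity lay between 800.4 and 800.5 on the arrays of type A, between 800.17 and 800.21 on type B and between 800.36 and 800.46 on type C. By a rule fixed before the data were examined, as were the comparisons, the gene lists, the rule for named genes and all alternatives except those described below as added, this scaling was kept. Each value was put on a log2 scale after adding the 25th percentile of its array type, which was 78.1, 126 and 106 for A, B and C. Control probe sets were removed. A probe set was tested when it lay above the 40th percentile on at least 2 arrays of its type. This left 26833 probe sets, 8515 on A, 8952 on B and 9366 on C, which represent 13411 genes. Of these, 21868 carried 1 gene symbol, 546 carried several and 4419 were not in the annotation used. Gene symbols came from probe set annotation, and gene positions from the GRCm38 mouse genome.

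Groups were compared with limma 3.58.1 in R 4.3.3, with 1 fit per array type and 1 mean per genotype and time, so that all groups of an array type share an estimate of the spread. In the groups with 1 array, that array is assumed to vary like the others. P-values are two-sided and were adjusted by Benjamini-Hochberg over the probe sets of all 3 array types, and a probe set was called at an adjusted p under 0.05. The comparisons were mutant against wild type at each time and as the mean of the 4 times with equal weight, oxygen against 0 h in each genotype, and the difference between genotypes in the response, at 72 h and by an F test over the 3 oxygen times. No replicate block was used, because the labels do not say that 1a or 1b marks a shared animal, batch or day. The changes in both genotypes were also correlated across probe sets. Genes are not independent replicates, so these correlations carry no test.

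The 25 gene lists were NRF2 targets of glutathione and detoxification, NRF2 targets of redox, iron and NADPH supply, other antioxidant enzymes, p53 targets and growth arrest, unfolded protein and amino acid stress, heat shock, metallothionein and acute phase, cell cycle, cytokines, chemokines and adhesion, interferon response, extracellular matrix and fibroblast, and markers of alveolar type 2, alveolar type 1, club, ciliated, endothelial, smooth muscle, cardiac muscle, skeletal muscle, fat, neutrophil, macrophage, T and NK, B and erythroid cells or tissue. Lists with at least 5 tested genes were compared with all other genes by camera in limma, with a preset correlation of 0.01 and then with an estimated correlation, adjusted over the lists of a comparison. Array type A was the main test. The adjustment ran within each array type. On B only detoxification targets and endothelial markers had enough tested genes, so adjusted values on B cover fewer lists than on A. Each gene entered with its brightest probe set. Member counts use all 3 array types, and are also given with p-values adjusted over the list alone.

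Genes were named by a rule. Nfe2l2 came first. For the mean genotype difference, for 72 h of oxygen in each genotype and for the difference in response at 72 h, the rule took the 8 largest rises and the 8 largest falls among called probe sets with 1 symbol. For the other comparisons it took the 4 largest of each. The arrays of the groups compared had to be without overlap, or, for the mean, all 4 genotype differences had to have the same sign, and the difference in response had no such condition. The rule added up to 4 members of each list with the smallest p-values, and Cdkn1a, Nqo1, Gclc, Gpx2, Hmox1, Mt1, Mt2, Sftpc, Scgb1a1, S100a8 and Hba-a1.

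The alternatives tried were a floor at the 25th percentile in place of the added value, quantile normalization, no filter on dim probe sets, a stricter filter at the 60th percentile, a fit with only the arrays of the groups compared, a replicate block, eBayes with trend and robust, array type A alone, and leaving out each of the 16 replicates in turn on all array types. Other settings were added after seeing the data, because the mutant 0 h arrays stood apart. They were the mean genotype difference over 24, 48 and 72 h only, the mutant under oxygen against wild type at 0 h, and the difference in response counted from 24 h. A squamous gene list, tests of genes near Nfe2l2 and near Xaf1, and 100 splits of the samples were chosen after seeing the data too.

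The pipeline was tested on simulated data with these group sizes, in which 100 probe sets changed 2-fold and 100 changed 4-fold. For the mean genotype difference it called 76 and 100 of them, with 9 unchanged probe sets called. For 72 h of oxygen it called 25 and 72 in wild type and 23 and 76 in the mutant. For the difference in response it called 6 and 39. A list shifted by 0.5 on the log2 scale was called, and 0 of 25 unchanged lists were. Genes were drawn independently there, so false calls in lists of correlated genes were not tested. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The number of arrays limits the precision.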

Results

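Lung RNA of wild type and Nrf2 mutant mice was compared before and during exposure to 100% oxygen. Nrf2, encoded by Nfe2l2, is a transcription factor that activates antioxidant and detoxification genes. Each group of 1 genotype and 1 time had 2 arrays of each type, except that the mutant at 0 h and wild type at 24 h had 1 array of type A (n = 1). Replicate 1b of these 2 groups is that array, so the counts given without it, where the group enters the comparison, come from array types B and C alone. Changes are given as log2 differences ± SE from limma with the adjusted p, and intensities as mean ± SD. Folds come from the fitted log2 differences, so the value added before the log2 makes them smaller than the ratio of the intensities. A difference against a group below the filter value of its array type (195, 272 and 211 on A, B and C) depends most on this added value. Lce3a, Defb4, Sprr3, Xaf1, Ces1f, Srxn1 and a dim probe set of Eln are among such cases, and no fold is given for these. Replicates correlated at r = 0.959 to 0.972 over 6 pairs on array type A, 0.916 to 0.959 over 8 pairs on B and 0.883 to 0.928 over 8 pairs on C. Arrays of the mutant at 0 h stood apart. Their mean correlation with the other arrays of their type was 0.856 on A, 0.827 to 0.838 on B and 0.848 to 0.858 on C, against 0.916 to 0.940, 0.892 to 0.922 and 0.879 to 0.902 for the other arrays. Their Gapdh 3' to 5' signal ratio, a measure of RNA integrity, was 1.67 to 2.26, and that of all other arrays was 0.858 to 1.54.

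Nfe2l2 itself (gene ID 18024, chromosome 2, 75675513 to 75704663 on GRCm38) was lower in every mutant array. Its intensity was 302.5 to 448.4 on the 7 mutant arrays and 2428 to 4488 on the 7 wild type arrays of type A. In wild type it was 2543 ± 163 (n = 2) at 0 h and 3775 ± 645 (n = 2) at 72 h, and in the mutant 448 (n = 1) and 347 ± 41.6 (n = 2). The mutant was lower by log2 -2.31 ± 0.25 at 0 h, -3.00 ± 0.25 at 24 h, -3.06 ± 0.21 at 48 h and -3.17 ± 0.21 at 72 h. Where the probes lie relative to the mutation is not known. Oxygen gave no called change of Nfe2l2 in either genotype (log2 0.55, adjusted p = 0.153 at 72 h in wild type).

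Which genes differed between genotypes on average was asked with the mean genotype difference over the 4 times. A large difference at some of the times can carry this mean. NRF2 targets of the glutathione, detoxification and redox lists were lower in the mutant. Gpx2, a glutathione peroxidase of epithelia, was 4.17-fold lower (log2 -2.06 ± 0.10, adjusted p = 4.2e-06). Ces1f, a carboxylesterase, was lower too (log2 -2.12 ± 0.09, adjusted p = 4.2e-07). The aldehyde oxidase Aox1 (log2 -1.92 ± 0.20), the glutathione transferase Gsta3 (log2 -1.61 ± 0.17), the carboxylesterase Ces1g (log2 -1.5 ± 0.11) and the glutathione synthesis gene Gclc (log2 -0.93 ± 0.11) were also lower. Of 26 measured glutathione and detoxification targets, 15 were lower, 0 higher and 11 not called, and 21 were lower when adjusted over the list alone. This list had a median of log2 -0.80 (adjusted p = 2.49e-24, and 0.000539 with an estimated correlation), and -0.46 over 6 genes on array type B (adjusted p = 9.75e-05, and 0.0234). Of 12 redox, iron and NADPH supply targets, 5 were lower and 0 higher, and 8 were lower when adjusted over the list alone (median log2 -0.40, adjusted p = 5.37e-06, and 0.0101 with an estimated correlation). They included Osgin1 (log2 -1.38 ± 0.10), an oxidative stress gene, and Txnrd1 (log2 -1.0 ± 0.10), the cytosolic thioredoxin reductase. Nqo1, a quinone reductase, was lower by a smaller amount (log2 -0.77 ± 0.10, adjusted p = 0.00472). Heme oxygenase Hmox1 was not called (log2 -0.30, adjusted p = 0.394), nor were the metallothioneins Mt1 (log2 -0.09, adjusted p = 0.861) and Mt2 (log2 0.06). Of 14 other antioxidant enzymes, 0 were called, and 0 when adjusted over the list alone (median log2 -0.0056, adjusted p = 0.818).

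Other genes with lower mean signal in the mutant were Cwc22, a splicing factor (log2 -3.58 ± 0.18, adjusted p = 1.19e-06), and Marco, a scavenger receptor of macrophages (log2 -1.47 ± 0.10, adjusted p = 4.08e-05). Other probe sets of Cwc22 gave smaller differences, so its size depends on the probe set. Matrix, smooth muscle and heat shock lists were higher. Of 19 extracellular matrix and fibroblast genes, 6 were higher and 0 lower, and 9 were higher when adjusted over the list alone (median log2 0.36, adjusted p = 3.14e-12, and 0.00273 with an estimated correlation). They included the collagens Col1a1 (log2 0.81 ± 0.10) and Col3a1 (log2 0.80 ± 0.09) and the matrix protein Tnc (log2 0.96 ± 0.14). Of 8 smooth muscle genes, 3 were higher, among them Tagln (log2 0.71 ± 0.08) and Myh11 (log2 0.71 ± 0.09), and 8 when adjusted over the list alone (median log2 0.46, adjusted p = 3.45e-11, and 0.00273 with an estimated correlation). Of 12 heat shock genes, 4 were higher and 0 lower, and 5 were higher when adjusted over the list alone (median log2 0.26, adjusted p = 4.65e-08, and 0.00509 with an estimated correlation). The chaperones Hspa1a (log2 1.68 ± 0.14) and Hspa1b (log2 1.30 ± 0.10) were among them. The largest rises also held Fam25c (log2 1.96 ± 0.11), Zfp979 (log2 1.41 ± 0.16), the peptidase Klk10 (log2 1.39 ± 0.14), Plekhg2 (log2 1.29 ± 0.19), Vnn3 (log2 1.29 ± 0.14) and Svep1 (log2 1.24 ± 0.19).

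The calls of 4 lists in the mean were lost with an estimated correlation. Skeletal muscle lost its call (median log2 0.47, adjusted p = 0.000838, adjusted p = 0.0724 with an estimated correlation), with 3 of 8 genes higher and 0 lower, and 4 higher and 1 lower when adjusted over the list alone. Neutrophil genes (median log2 -0.44, 0.00361 and 0.0524) had 2 of 11 lower, and 6 lower and 1 higher when adjusted over the list alone. P53 targets (median log2 0.18, 0.0082 and 0.0724) had 0 of 17 called and 3 higher when adjusted over the list alone. Interferon response (median log2 -0.15, 0.0193 and 0.102) had 0 of 16 called and 2 lower when adjusted over the list alone. The neutrophil gene S100a8 (log2 -0.76 ± 0.08, adjusted p = 0.00106) and the chemokine Cxcl5 (log2 -0.94 ± 0.12) were lower in the mean. The genotype difference of S100a8 changed sign, from log2 0.28 at 0 h and 1.26 at 24 h to -2.55 at 48 h and -2.05 at 72 h. Cardiac muscle had a median of log2 0.02, a mean of -0.09 and a test in the lower direction (adjusted p = 0.818). T and NK cells had a median of log2 0.03, a mean of -0.0036 and a test in the higher direction (adjusted p = 0.818).

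In all, 415 probe sets (337 genes) differed in the mean, 197 higher and 218 lower in the mutant, and 83 of them by more than 2-fold. With the mutant 0 h arrays left aside, in a mean over 24, 48 and 72 h chosen after seeing the data, 336 were called, 158 higher and 178 lower, and 238 of these were among the 415. In that mean the skeletal muscle list had a median of log2 0.02 (adjusted p = 0.94), and Fam25c (log2 0.47, adjusted p = 0.118), Klk10 (log2 0.41, adjusted p = 0.364), Cxcl5 (log2 -0.54, adjusted p = 0.101) and the skeletal actin Acta1 (log2 0.27, adjusted p = 0.589) were not called. Heat shock had a median of log2 0.27 there (adjusted p = 0.0012), with Hspa1a at log2 1.32 and Hspa1b at log2 0.63 (adjusted p = 0.0178). The glutathione and detoxification list there had a median of log2 -0.81 (adjusted p = 1.68e-26). Leaving out single samples gave 157 without mutant 0 h replicate 1b, 106 without wild type 24 h replicate 1b, 268 without wild type 48 h replicate 1a and 260 without wild type 48 h replicate 1b.

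**Figure D1:**
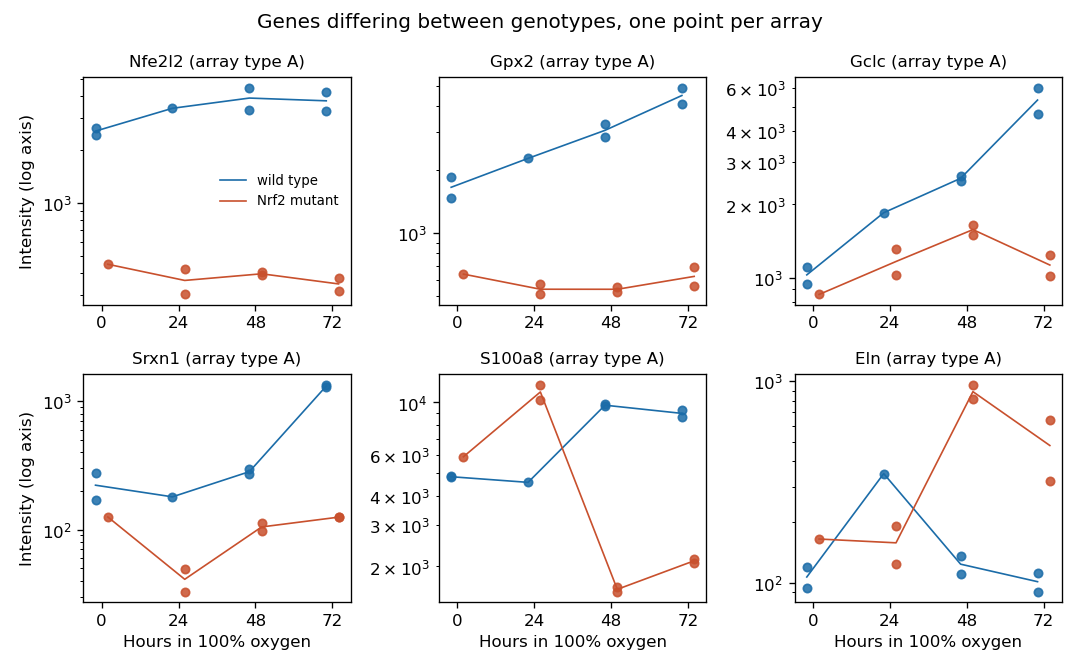
Intensity on a log axis against hours in 100% oxygen for Nfe2l2, Gpx2, Gclc, Srxn1, S100a8 and Eln, with 1 point per array, shifted sideways for legibility, and lines through the group means of wild type and mutant. Nfe2l2 stays between 302.5 and 448.4 on the mutant arrays and between 2428 and 4488 on the wild type arrays. The Srxn1 and Eln panels show dimmer probe sets of these genes.

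The difference that was present before oxygen was asked at 0 h. Some genes of squamous epithelium were higher in the mutant. Of 27 measured genes in a squamous list chosen after seeing the data, 10 were higher and 0 lower (median log2 0.63). Lce3a, a protein of the cornified envelope, was among them (log2 8.17 ± 0.36, adjusted p = 1.5e-07), with an intensity of 42700 to 52550 on the 2 mutant 0 h arrays, and at most 327.7 on the other 14 arrays of type C. The defensin Defb4 (log2 6.66 ± 0.25), Fam25c (log2 6.43 ± 0.22) and the small proline-rich protein Sprr3 (log2 5.38 ± 0.49, adjusted p = 0.000389) were higher too. Of 8 skeletal muscle genes, 5 were higher and 0 lower, and 6 higher and 1 lower when adjusted over the list alone (median log2 1.76, adjusted p = 8.87e-07, and 0.0438 with an estimated correlation). Acta1 (log2 3.54 ± 0.30) and the troponins Tnnc2 (log2 3.18 ± 0.30) and Tnnt3 (log2 2.73) were among them. Of 12 heat shock genes, 4 were higher, among them Hspa1b (log2 3.34 ± 0.21) and Hspa1a (log2 2.78 ± 0.30), and 6 when adjusted over the list alone (median log2 0.83, adjusted p = 4.98e-06, and 0.0404 with an estimated correlation). On array type B, 6 endothelial genes were lower as a list (median log2 -0.57, adjusted p = 0.0119, and 0.045 with an estimated correlation). Of all 17, 1 was lower, and 5 when adjusted over the list alone, and the 15 on array type A were not called (median log2 -0.41, adjusted p = 0.351). These groups moved on the arrays that stood apart.

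Some detoxification genes were already lower at 0 h. Of 26 targets, 7 were lower and 0 higher, and 11 were lower when adjusted over the list alone (median log2 -0.61, adjusted p = 0.00124, and 0.0438 with an estimated correlation). The list test is from array type A, which has 1 mutant 0 h array. These differences too rest on the mutant 0 h arrays, which stood apart on every array type. On array type B, with 2, the 6 genes measured were not called as a list (median log2 -0.047, adjusted p = 0.488). Gpx2 (log2 -1.26 ± 0.22, adjusted p = 0.0183), the transporter Abcc3 (log2 -2.08) and the epoxide hydrolase Ephx1 (log2 -1.05) were among them. Cwc22 (log2 -3.52 ± 0.37), the growth factor gene Tgfb1 (log2 -2.41 ± 0.39) and an immunoglobulin heavy chain probe set, Ighm (log2 -2.44 ± 0.19), were lower, while the brightest Ighm probe set was not called (log2 -0.75). Interferon response (median log2 -0.41, adjusted p = 0.0326, adjusted p = 0.179 with an estimated correlation) and extracellular matrix (median log2 0.12, adjusted p = 0.00925, adjusted p = 0.112 with an estimated correlation) lost their calls. The first had 1 of 16 genes lower, and 4 when adjusted over the list alone. The second had 3 of 19 genes higher, and 5 when adjusted over the list alone. In all, 738 probe sets differed, 393 higher and 345 lower. The count was 164 without wild type 0 h replicate 1a, 277 without wild type 0 h replicate 1b and 152 without mutant 0 h replicate 1b.

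After 24 h in oxygen, few probe sets were called between genotypes. Wild type had 1 array of type A there, on which the list tests of that type rest. All 11 measured neutrophil genes lie on type A. In the main fit, the number of probe sets at an unadjusted p under 0.05 in limma was no lower than at 48 h or 72 h. The low count therefore does not show that fewer genes differed. Xaf1, an interferon-induced factor that opposes an apoptosis inhibitor, was lower in the mutant (log2 -4.94 ± 0.37, adjusted p = 0.000202). Cwc22 (log2 -3.71 ± 0.37), Ces1f (log2 -2.79 ± 0.19), Gpx2 (log2 -1.92 ± 0.22) and Ces1g (log2 -1.92 ± 0.25) were lower. Vnn3 (log2 2.23 ± 0.31), the nuclear receptor Nr4a1 (log2 2.0 ± 0.30), the collagen Col9a1 (log2 1.93 ± 0.30) and the kinase Taok1 (log2 1.92 ± 0.27) were higher. Detoxification targets had 2 of 26 genes lower, and 9 when adjusted over the list alone (median log2 -0.58, adjusted p = 3.06e-09, and 0.00864 with an estimated correlation), but were not called on array type B (median log2 -0.23, adjusted p = 0.146). Neutrophil genes were higher as a list (median log2 0.96, adjusted p = 6.51e-05, and 0.0346 with an estimated correlation), with S100a8 (log2 1.26 ± 0.18, adjusted p = 0.0256) the 1 of 11 called, and 6 higher and 1 lower when adjusted over the list alone. Alveolar type 1 (median log2 -0.69, adjusted p = 0.01, adjusted p = 0.115 with an estimated correlation) and smooth muscle (median log2 0.31, adjusted p = 0.0147, adjusted p = 0.115 with an estimated correlation) lost their calls. In all, 42 probe sets differed, 21 in each direction. The count was 5 without wild type 24 h replicate 1b, 18 without mutant 24 h replicate 1a and 21 without mutant 24 h replicate 1b. On the arrays of these groups alone, limma called 0, with 2539 at an unadjusted p under 0.05.

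At 48 h, neutrophil and detoxification genes were lower in the mutant. S100a8, a calcium-binding protein abundant in neutrophils, was 5.86-fold lower (log2 -2.55 ± 0.15, adjusted p = 6.47e-05), with an intensity of 1598 ± 52.1 (n = 2) against 9735 ± 124 (n = 2) in wild type. Of 11 neutrophil genes, 6 were lower, among them S100a9 (log2 -2.34 ± 0.20), the collagenase Mmp8 (log2 -2.85 ± 0.34) and the chemokine receptor Cxcr2 (log2 -1.77), and 8 when adjusted over the list alone (median log2 -1.77, adjusted p = 7.14e-11, and 0.00395 with an estimated correlation). The cytokine Il1b was lower (log2 -1.53 ± 0.17). Detoxification targets had 5 of 26 genes lower, and 16 when adjusted over the list alone (median log2 -0.71, adjusted p = 2.15e-15, and 0.00205 with an estimated correlation), with Gpx2 at log2 -2.34 ± 0.18. On array type B their call was lost (median log2 -0.40, adjusted p = 0.0163, adjusted p = 0.135 with an estimated correlation). Redox targets had 2 of 12 lower, Osgin1 (log2 -1.68 ± 0.19) and Txnrd1 (log2 -1.10), and 3 when adjusted over the list alone (median log2 -0.41, adjusted p = 8.15e-05, and 0.0162 with an estimated correlation). Heat shock (1 of 12 genes higher, 6 when adjusted over the list alone, median log2 0.46, 0.00687 with an estimated correlation), extracellular matrix (2 of 19, 9 when adjusted over the list alone, median log2 0.51, 0.0069) and smooth muscle (2 of 8, 5 when adjusted over the list alone, median log2 0.75, 0.00687) were higher as lists.

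Among the largest differences at 48 h, the matrix protein Spon2 (log2 2.75 ± 0.30), Rprml (log2 2.53 ± 0.33), Hspa1a (log2 2.26 ± 0.29 on array type C) and a dimmer probe set of the elastin gene Eln (log2 2.26 ± 0.26) were higher. Xaf1 (log2 -4.17 ± 0.37) and Cwc22 (log2 -3.91) were lower. P53 targets lost their call (median log2 0.43, adjusted p = 0.00261, adjusted p = 0.0518 with an estimated correlation), as did alveolar type 1 (median log2 0.21, 0.0476 and 0.131) and cardiac muscle (median log2 -0.24, 0.0488 and 0.131). In all, 101 probe sets differed, 32 higher and 69 lower. The count was 36 without wild type 48 h replicate 1a, 30 without wild type 48 h replicate 1b, 35 without mutant 48 h replicate 1a and 42 without mutant 48 h replicate 1b. It was 19 on the arrays of these groups alone.

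At 72 h, NRF2 targets were lower in the mutant. The sulfiredoxin gene Srxn1 was lower (log2 -2.78 ± 0.19, adjusted p = 8.16e-05) by 1 probe set, while its brighter probe set was not called (log2 0.26). Gpx2 was 6.53-fold lower (log2 -2.71 ± 0.18, adjusted p = 8.16e-05), the cystine transporter Slc7a11 was lower by log2 -2.30 ± 0.21, and Gclc was 4.49-fold lower (log2 -2.17 ± 0.19, adjusted p = 0.000556). Of 26 detoxification targets, 11 were lower and 0 higher, and 20 were lower when adjusted over the list alone (median log2 -1.05, adjusted p = 2.17e-22, and 0.000689 with an estimated correlation), and the call held on array type B (median log2 -0.80, adjusted p = 8.97e-06, and 0.0126). Of 12 redox targets, 5 were lower, among them Osgin1 (log2 -2.39 ± 0.19) and Txnrd1 (log2 -1.72 ± 0.17), and 7 when adjusted over the list alone (median log2 -0.51, adjusted p = 5.01e-05, and 0.0165 with an estimated correlation). Of 11 neutrophil genes, 3 were lower, among them S100a8 (log2 -2.05 ± 0.15) and S100a9 (log2 -1.75), and 6 lower and 1 higher when adjusted over the list alone (median log2 -0.93, adjusted p = 3.5e-05, and 0.0165 with an estimated correlation).

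Smooth muscle and matrix genes were higher in the mutant at 72 h. Of 8 smooth muscle genes, 4 were higher, among them Tagln (log2 1.47 ± 0.15) and the calponin Cnn1 (log2 1.32), and 6 when adjusted over the list alone (median log2 1.04, adjusted p = 4.17e-12, and 0.00218 with an estimated correlation). Of 19 matrix genes, 3 were higher, among them Col1a1 (log2 1.28 ± 0.18) and Tnc (log2 1.63 ± 0.25), and 10 when adjusted over the list alone (median log2 0.57, adjusted p = 3.26e-13, and 0.00218 with an estimated correlation). Rprml (log2 3.29 ± 0.33), the macrophage lectin Mgl2 (log2 3.09 ± 0.41), Zfp979 (log2 2.30 ± 0.32) and the vasoconstrictor gene Edn1 (log2 2.29 ± 0.30) were the largest rises. Xaf1 (log2 -5.17 ± 0.37), Cwc22 (log2 -3.18) and Nfe2l2 (log2 -3.17) were, with Srxn1, the largest falls named by the rule. Alveolar type 1 lost its call (median log2 -0.36, adjusted p = 0.0144, adjusted p = 0.095 with an estimated correlation). In all, 220 probe sets differed, 95 higher and 125 lower. The count was 81 without wild type 72 h replicate 1a, 74 without wild type 72 h replicate 1b, 105 without mutant 72 h replicate 1a and 96 without mutant 72 h replicate 1b. It was 27 on the arrays of these groups alone.

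The response of wild type lung to oxygen was asked against 0 h. On array type A, wild type at 24 h had 1 array, on which the tests of that type at 24 h rest. By 24 h, Xaf1 was higher (log2 5.63 ± 0.37, adjusted p = 4.55e-05), at an intensity of 3398 to 10000 on the 6 wild type oxygen arrays and 87.0 to 92.3 at 0 h. Hspa1b was 16.1-fold higher (log2 4.01 ± 0.21), Hspa1a by log2 4.02 ± 0.30 and Col1a1 by log2 2.90 ± 0.22. Cdkn1a, the growth arrest gene activated by p53, was 5.07-fold higher (log2 2.34 ± 0.24, adjusted p = 0.00157). The centriole gene Poc1a (log2 -3.19 ± 0.28), the lymphocyte activation gene Cd69 (log2 -2.57 ± 0.23), the DNA polymerase Polb (log2 -2.28 ± 0.45) and the adaptor Tradd (log2 -2.25 ± 0.37) fell. Heat shock (5 of 12 genes higher, 6 when adjusted over the list alone, median log2 0.94, 0.00932 with an estimated correlation), matrix (7 of 19, 9 when adjusted over the list alone, median log2 0.54, 0.00932) and endothelial genes (2 of 17, 6 when adjusted over the list alone, median log2 0.47, 0.0392) rose as lists, the last also on array type B (median log2 0.62, adjusted p = 0.000242, and 0.00857). Cardiac muscle (3 of 11 genes lower, 5 when adjusted over the list alone, median log2 -0.42, 0.0392 with an estimated correlation), T and NK (3 of 10, 5 when adjusted over the list alone, median log2 -1.09, 0.0345) and B cell genes (1 of 7, 5 when adjusted over the list alone, median log2 -0.98, 0.0204) fell as lists. In all, 462 probe sets changed, 258 higher and 204 lower. The count was 141 without wild type 0 h replicate 1a and 102 without wild type 0 h replicate 1b. It was 244 without wild type 24 h replicate 1a, 47 without wild type 24 h replicate 1b and 49 on the arrays of these groups alone.

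By 48 h in wild type, Hspa1a (log2 4.42 ± 0.25), Xaf1 (log2 4.36 ± 0.37), Hspa1b (log2 4.31 ± 0.17) and Mmp8 (log2 3.10 ± 0.34) had risen most. Poc1a (log2 -3.06), the plasma cell gene Mzb1 (log2 -2.91 ± 0.25), Tmem14c (log2 -2.59 ± 0.18) and Rprml (log2 -2.52 ± 0.33) had fallen most. Of 11 neutrophil genes, 7 rose, with S100a8 at log2 1.0 ± 0.15, and 8 when adjusted over the list alone (median log2 1.0, 0.0104 with an estimated correlation). Lists that rose and held their call with an estimated correlation were also redox targets (7 of 12 genes, and 7 when adjusted over the list alone, median log2 0.78, 0.0362) and unfolded protein stress (8 of 14, and 12, median log2 0.81, 0.0315). So did heat shock (7 of 12 with 1 lower, and 7 with 1 lower, median log2 1.03, 0.0104) and matrix (8 of 19, and 10 with 1 lower, median log2 0.80, 0.0194). Endothelial genes rose and held their call on array type B (median log2 0.78, adjusted p = 0.00109, and 0.0151 with an estimated correlation) and lost it on A (4 of 17 higher, and 8, median log2 0.46, adjusted p = 0.00263, and 0.0627). The adjustment on A ran over more lists. Cardiac muscle (8 of 11 lower, and 10, median log2 -1.04, 0.0104), T and NK (6 of 10, and 7, median log2 -0.99, 0.0315) and B cell genes (7 of 7, and 7, median log2 -1.17, 0.0104) fell as lists. In all, 1783 probe sets changed, 873 higher and 910 lower. The count was 609 without wild type 0 h replicate 1a and 493 without wild type 0 h replicate 1b. It was 421 without wild type 48 h replicate 1a, 497 without wild type 48 h replicate 1b and 584 on the arrays of these groups alone.

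By 72 h in wild type, the lists of p53 targets, unfolded protein and amino acid stress and redox NRF2 targets had risen. Cdkn1a rose 8.74-fold (log2 3.13 ± 0.20, adjusted p = 3.06e-05), from an intensity of 450.6 to 4545 ± 331 (n = 2). The metal-binding Mt1 rose 9.27-fold (log2 3.21 ± 0.24, adjusted p = 6.36e-05) and Lyve1, a receptor of lymphatic endothelium, 10.2-fold (log2 3.35 ± 0.20, adjusted p = 6.28e-06). Xaf1 (log2 5.25 ± 0.37), Gm13889 (log2 3.71 ± 0.41), the coagulation starter F3 (log2 3.31 ± 0.25), Ier5l (log2 3.17 ± 0.24) and the pantetheinase Vnn1 (log2 3.11 ± 0.29) completed the largest rises. Redox targets rose in 6 of 12, and 7 when adjusted over the list alone (median log2 0.78, adjusted p = 0.000114, and 0.0208 with an estimated correlation), with Osgin1 at log2 2.41 ± 0.19 and Hmox1 at log2 1.58 ± 0.24. Detoxification targets rose in 7 of 26 with 1 lower, and in 10 with 2 lower when adjusted over the list alone (median log2 0.19, adjusted p = 0.0488, adjusted p = 0.0846 with an estimated correlation). On array type B, 6 of these genes rose as a list and held the call (median log2 0.91, adjusted p = 0.00362, and 0.0372 with an estimated correlation). Slc7a11 (log2 2.72 ± 0.21), Gclc (log2 2.29 ± 0.19) and Gpx2 (log2 1.41 ± 0.18) rose, and Nqo1 was not called (log2 0.44, adjusted p = 0.208). P53 targets rose in 5 of 17, among them Sesn2 (log2 2.75 ± 0.27) and Gadd45a (log2 2.17 ± 0.19), and in 9 with 1 lower when adjusted over the list alone (median log2 0.76, 0.0208 with an estimated correlation). Unfolded protein and amino acid stress genes rose in 10 of 14, among them Chac1 (log2 2.09 ± 0.15) and Atf4 (log2 1.70), and in 12 when adjusted over the list alone (median log2 0.93, 0.0208).

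Inflammatory genes rose and lymphocyte and heart muscle genes fell in wild type at 72 h. Metallothionein and acute phase genes rose in 8 of 11, and in 8 with 2 lower when adjusted over the list alone (median log2 1.5, 0.0208 with an estimated correlation), with the serum amyloid Saa3 at log2 2.35. Cytokines, chemokines and adhesion genes rose in 10 of 18 with 1 lower, among them the monocyte attractant Ccl2 (log2 2.60 ± 0.20) and Cxcl1 (log2 2.12), and in 11 with 2 lower when adjusted over the list alone (median log2 0.78, 0.031). Neutrophil genes rose in 5 of 11, with Mmp8 at log2 2.91, and 7 when adjusted over the list alone (median log2 0.81, 0.0253). Macrophage genes rose in 5 of 13, with Marco at log2 1.77, and in 5 with 1 lower when adjusted over the list alone (median log2 0.40, 0.0384). Interferon response fell in 5 of 16 with 1 higher, and in 6 with 1 higher when adjusted over the list alone (median log2 -0.49, 0.0392), with the guanylate-binding Gbp3 at log2 -2.24 ± 0.18. T and NK genes fell in 6 of 10, with Cd3g at log2 -1.89, and 7 when adjusted over the list alone (median log2 -0.93, 0.0208), and B cell genes in 7 of 7, and 7 when adjusted over the list alone, with Ms4a1 at log2 -1.98 (median log2 -1.21, 0.0193). Cardiac muscle genes fell in 9 of 11, and 10 when adjusted over the list alone (median log2 -1.42, 0.0141), with the atrial light chain Myl7 at log2 -3.10 ± 0.16. Poc1a (log2 -3.51 ± 0.28), the muscle protein Csrp3 (log2 -3.23 ± 0.25) and Rprml (log2 -3.13 ± 0.33) were among the largest falls. So were Acta1 (log2 -3.08 ± 0.25), Mzb1 (log2 -3.08 ± 0.25), the fatty acid carrier Fabp1 (log2 -3.06 ± 0.17) and Mgl2 (log2 -3.05 ± 0.41).

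The remaining lists in wild type at 72 h had no call that held on array type A. Heat shock (4 of 12 higher and 1 lower, and 5 higher and 1 lower when adjusted over the list alone, median log2 0.49, adjusted p = 0.0129, adjusted p = 0.0565 with an estimated correlation) and cell cycle (4 of 25 lower, and 4 lower and 1 higher, median log2 -0.41, 0.00617 and 0.109) lost theirs. Matrix (6 of 19 higher and 2 lower, and 10 higher and 2 lower, median log2 0.59, 0.00818 and 0.0565), skeletal muscle (3 of 8 lower, and 4, median log2 -0.72, 0.00357 and 0.0667) and alveolar type 1 (median log2 -0.47, 0.0281 and 0.082) lost theirs. Other antioxidant enzymes (adjusted p = 0.0838), club (0.66), endothelial (0.103) and, on array type C, ciliated cells (0.681) were not called. On array type B, however, 6 endothelial genes rose as a list, adjusted over fewer lists (median log2 0.69, adjusted p = 0.0068, and 0.0372 with an estimated correlation). Alveolar type 2 (0.786, median log2 0.02, mean -0.03, test lower) and smooth muscle (0.786, median log2 -0.07, mean 0.04, test lower) were not called either. The alveolar surfactant gene Sftpc (log2 0.19) and the club cell gene Scgb1a1 (log2 0.47) were not called. Too few genes of the fat and erythroid lists were measured for a test. Fat had 1 of 5 lower, Adipoq (log2 -1.40), and erythroid had 2 of 3 lower, among them the heme synthesis gene Alas2 (log2 -0.75). In all, 2100 probe sets (1707 genes) changed, 1143 higher and 957 lower. The count was 981 without wild type 0 h replicate 1a and 820 without wild type 0 h replicate 1b. It was 1065 without wild type 72 h replicate 1a, 815 without wild type 72 h replicate 1b and 586 on the arrays of these groups alone.

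**Figure D2:**
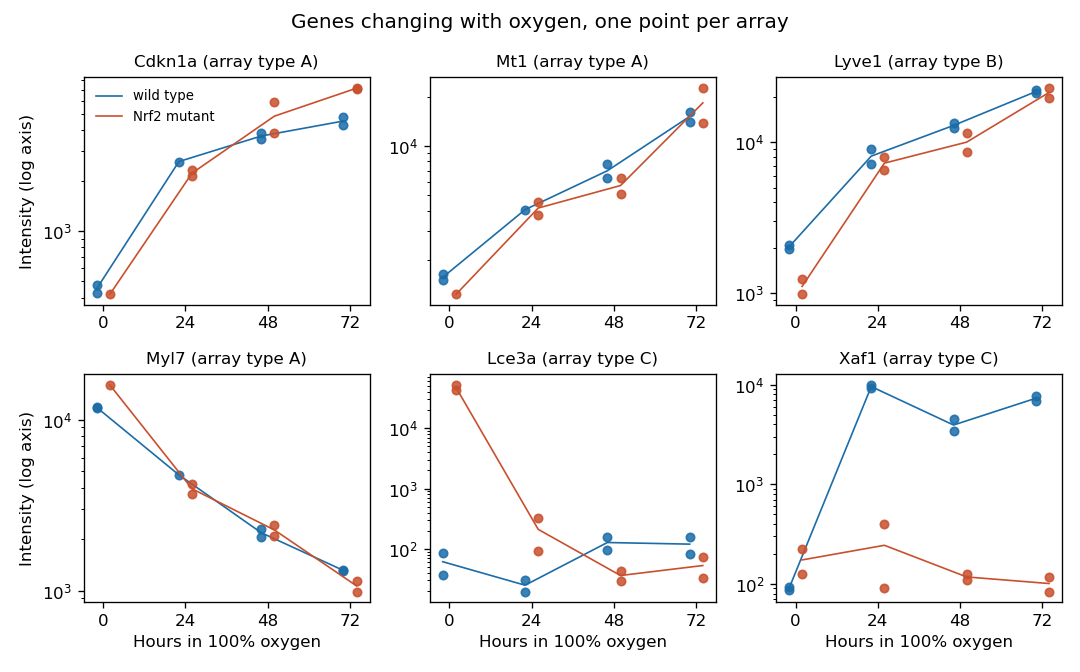
Intensity on a log axis against hours in 100% oxygen for Cdkn1a, Mt1, Lyve1, Myl7, Lce3a and Xaf1, with 1 point per array, shifted sideways for legibility, and lines through the group means of each genotype. Cdkn1a reaches a mean of 4545 at 72 h in wild type, and Lce3a lies above 327.7 only on the mutant 0 h arrays.

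The response of the mutant to oxygen was asked against its own 0 h arrays, which stood apart. At 24 h the growth factor Tgfb1 (log2 3.57 ± 0.39), the sialyltransferase St3gal1 (log2 4.08 ± 0.48), Kmt2e (log2 3.35 ± 0.67) and the hemoglobin gene Hba-a1 (log2 4.19 ± 1.26) were the largest rises. Hba-a1 had a similar change in wild type at 24 h that was not called (log2 3.76 ± 1.26). Lce3a (log2 -7.34 ± 0.36), Defb4 (log2 -6.88 ± 0.25), Fam25c (log2 -5.73 ± 0.22) and the keratinocyte gene Krtdap (log2 -5.39 ± 0.38) were the largest falls. Cdkn1a rose 4.63-fold (log2 2.21 ± 0.24, adjusted p = 0.000232). Against wild type 0 h, Lce3a (log2 0.83, adjusted p = 0.176), Defb4 (log2 -0.22, adjusted p = 0.66) and Krtdap (log2 -0.42, adjusted p = 0.458) were not called. Cdkn1a was called (log2 2.12, adjusted p = 0.000371). No list of array type A held its call with an estimated correlation at 24 h. Endothelial cells did on type B (median log2 1.16, adjusted p = 0.0156 with an estimated correlation), counted from 0 h arrays on which this list was lower than in wild type (median log2 -0.57). In all, 6539 probe sets changed, 3285 higher and 3254 lower, and 2745 changed against wild type 0 h, 2275 of them shared. The count was 2121 without mutant 0 h replicate 1b, 4112 without mutant 24 h replicate 1a and 3764 on the arrays of these groups alone.

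At 48 h in the mutant, the stress sensor Sesn2 (log2 3.89 ± 0.27), the cytokine signal suppressor Socs3 (log2 3.78 ± 0.25), Vnn1 (log2 3.64 ± 0.29), St3gal1 (log2 3.45 ± 0.48) and Cdkn1a (log2 3.29 ± 0.24) rose. Lce3a (log2 -8.39), Krtdap (log2 -6.70), Defb4 (log2 -6.70) and Fam25c (log2 -5.86) fell on the same baseline. S100a8 fell too (log2 -1.83 ± 0.18, adjusted p = 0.000181). Cardiac muscle genes fell in 9 of 11, and 10 when adjusted over the list alone (median log2 -1.99, adjusted p = 1.47e-07, and 0.0257 with an estimated correlation). Endothelial genes rose as a list on array type B, from the same low 0 h level (median log2 1.13, adjusted p = 0.000536, and 0.0115 with an estimated correlation). On A their call was lost (median log2 0.59, adjusted p = 0.00722, and 0.12). In all, 4799 probe sets changed, 2579 higher and 2220 lower, and 1731 changed against wild type 0 h, 1276 of them shared. The count was 1508 without mutant 0 h replicate 1b, 2381 without mutant 48 h replicate 1a and 2227 on the arrays of these groups alone.

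At 72 h in the mutant, Cdkn1a rose 14.6-fold (log2 3.87 ± 0.24, adjusted p = 8.07e-06), to an intensity of 7145 ± 87.3 (n = 2), and Mt1 13.7-fold (log2 3.78 ± 0.29, adjusted p = 2.81e-05). Lyve1 rose 17.5-fold (log2 4.13 ± 0.20, adjusted p = 1.42e-07). Gm13889 (log2 4.60 ± 0.41), Socs3 (log2 4.27 ± 0.25 by its dimmer probe set), Tinagl1 (log2 4.14 ± 0.33), the scaffold protein Akap12 (log2 3.99 ± 0.33), Myrip (log2 3.81 ± 0.44), Trib3 (log2 3.05 ± 0.22), Ccl2 (log2 2.50) and Hmox1 (log2 1.5) rose. Gclc (log2 0.37, adjusted p = 0.317), Gpx2 (log2 -0.04, adjusted p = 0.933) and Nqo1 (log2 -0.43, adjusted p = 0.233) were not called. Cardiac muscle genes fell in 8 of 11, and 9 when adjusted over the list alone (median log2 -2.07, adjusted p = 1.46e-06, and 0.0371 with an estimated correlation), with Myl7 at log2 -3.82 ± 0.19. Lce3a (log2 -8.24 ± 0.36), Defb4 (log2 -6.82 ± 0.25), Krtdap (log2 -6.42 ± 0.38), Fam25c (log2 -6.35 ± 0.22), Acta1 (log2 -6.00 ± 0.30), Sprr3 (log2 -5.15 ± 0.49), and the muscle light chains Myl3 (log2 -4.91 ± 0.22) and Myl1 (log2 -4.49 ± 0.22) fell from their level on the 0 h arrays.

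Lists in the mutant at 72 h that lost their call with an estimated correlation included unfolded protein stress (8 of 14 higher, and 11 when adjusted over the list alone, median log2 0.73, adjusted p = 3.58e-05, adjusted p = 0.0638 with an estimated correlation) and metallothionein and acute phase (8 of 11 higher and 1 lower, and 8 and 1, median log2 1.69, 0.00188 and 0.0638). Others were matrix (9 of 19 higher, and 10, median log2 0.72, 0.00307 and 0.0638) and skeletal muscle (6 of 8 lower, and 7, median log2 -2.27, 1.94e-05 and 0.0638). P53 targets were not called as a list (9 of 17 higher and 2 lower, and 9 and 2 when adjusted over the list alone, median log2 1.20, adjusted p = 0.0531). Endothelial genes rose as a list on array type B (median log2 1.34, adjusted p = 0.0115, and 0.0442 with an estimated correlation), again from 0 h arrays on which they were low. On array type A their call was lost (median log2 0.72, adjusted p = 0.0215, adjusted p = 0.128 with an estimated correlation), and against wild type 0 h the list on A had a median of log2 0.16 (adjusted p = 0.0153). Heat shock had a median of log2 0.11, a mean of -0.30 and a test in the lower direction (adjusted p = 0.305). Against wild type 0 h, the mutant at 72 h gave Cdkn1a at log2 3.77, Mt1 at 3.45 and Lyve1 at 3.32. Gpx2 (log2 -1.30, adjusted p = 0.00132) and Nqo1 (log2 -0.85, adjusted p = 0.015) were lower, and Lce3a (log2 -0.07, adjusted p = 0.938) and Defb4 (log2 -0.16, adjusted p = 0.763) were not called. On that baseline the detoxification list was lower (median log2 -0.85, adjusted p = 3.57e-05), cardiac muscle lower (median log2 -1.68, adjusted p = 1.56e-07), and matrix higher (median log2 0.85, adjusted p = 5.09e-07). P53 targets (median log2 0.83, adjusted p = 0.000125), unfolded protein stress (0.78, 7.52e-07), metallothionein and acute phase (1.30, 1.04e-05) and cytokine genes (0.69, 0.000694) were higher there. B cell (-1.34, 1.04e-05), T and NK (-1.22, 0.000361) and interferon genes (-0.47, 0.000974) were lower. Redox targets (0.13, 0.196) and neutrophil genes (-0.10, 0.89) were not called. These tests used the preset correlation only. In all, 5782 probe sets (4276 genes) changed, 2959 higher and 2823 lower, and 3461 changed against wild type 0 h, 2613 of them shared. The count was 2043 without mutant 0 h replicate 1b, 3757 without mutant 72 h replicate 1a and 2717 on the arrays of these groups alone.

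**Figure D3:**
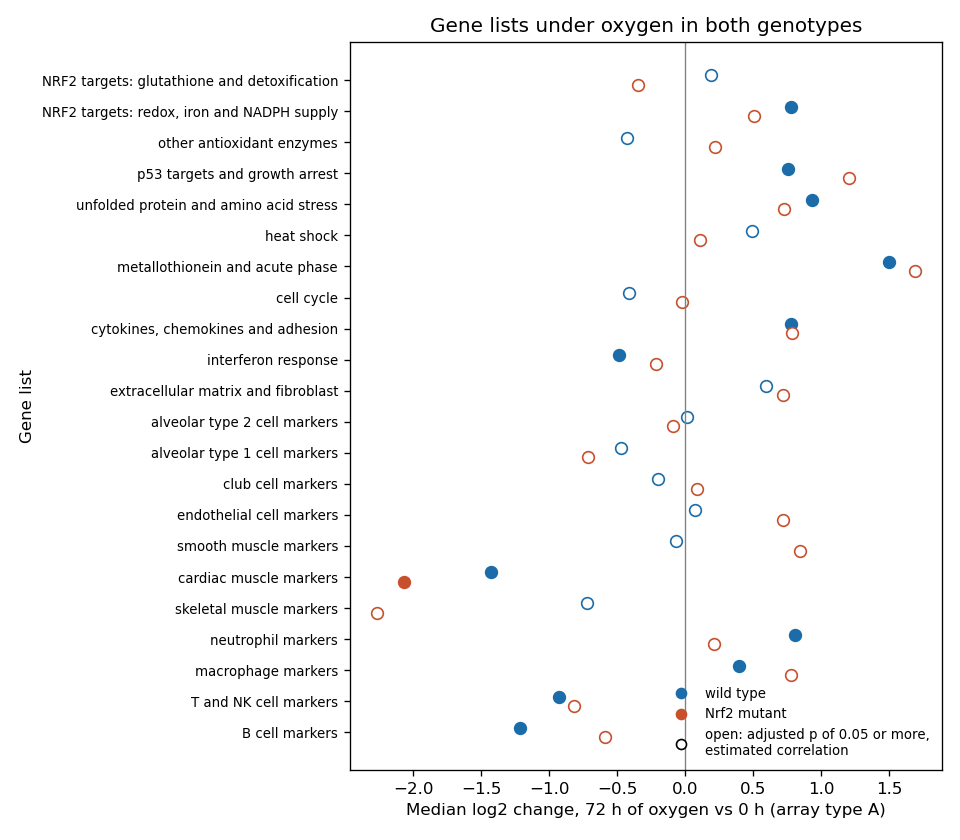
Median log2 change at 72 h of oxygen against 0 h for each gene list on array type A, in blue for wild type and orange for the mutant, with filled points for an adjusted p under 0.05 with an estimated correlation and open points otherwise. Cardiac muscle is lowest in wild type at -1.42 and is filled in both genotypes.

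Whether the response to oxygen differed between genotypes was asked at 72 h. Of the NRF2 targets, Slc7a11 (log2 -2.40 ± 0.30, adjusted p = 0.00265), Osgin1 (log2 -2.02 ± 0.27, adjusted p = 0.00384), Gclc (log2 -1.92 ± 0.30, adjusted p = 0.0163) and Gpx2 (log2 -1.45 ± 0.29, adjusted p = 0.0441) had a lower response in the mutant. Hmox1, which rose in wild type, had no called difference (log2 -0.08, adjusted p = 0.955). The neutrophil genes S100a8 (log2 -2.33 ± 0.23, adjusted p = 0.00133) and S100a9 (log2 -2.90 ± 0.32) had a lower response, and the smooth muscle gene Cnn1 a higher one (log2 2.13 ± 0.24). Counted from 24 h, a baseline chosen after seeing the data, S100a8 (log2 -3.31 ± 0.23), S100a9 (log2 -2.94 ± 0.32) and Slc7a11 (log2 -2.06 ± 0.30, adjusted p = 0.0211) were called. Gclc (log2 -1.53, adjusted p = 0.121), Gpx2 (log2 -0.79, adjusted p = 0.546) and Osgin1 (log2 -1.34, adjusted p = 0.0989) were not. On array type A, for genes and lists alike, the wild type part of the 24 h baseline is 1 array. The other largest differences in response at 72 h included Mgl2 (log2 3.84 ± 0.57), Rprml (log2 3.68 ± 0.46), Lce3a (log2 -8.67 ± 0.51) and Xaf1 (log2 -5.67 ± 0.53).

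No list held its call for the difference in response with an estimated correlation. Detoxification targets (3 of 26 lower, and 10 lower and 1 higher when adjusted over the list alone, median log2 -0.60, adjusted p = 0.00494, adjusted p = 0.0576 with an estimated correlation) and heat shock (3 of 12 lower, and 4, median log2 -0.70, 0.000978 and 0.0517) had been called with the preset one. So had smooth muscle (2 of 8 higher, and 6, median log2 1.02, 0.000882 and 0.0517), skeletal muscle (2 of 8 lower, and 6, median log2 -1.68, 3.75e-06 and 0.0517) and neutrophil genes (2 of 11 lower, and 5 lower and 2 higher, median log2 -1.02, 0.00604 and 0.0672). Redox targets were not called (2 of 12 lower, and 4 lower and 1 higher, median log2 -0.20, adjusted p = 0.207). From 24 h, neutrophil genes (median log2 -1.57, adjusted p = 3.87e-09) and matrix genes (median log2 0.68, adjusted p = 6.71e-06) were called with the preset correlation, and skeletal muscle had a median of log2 0.09. Smooth muscle (median log2 0.51, adjusted p = 0.000581) and other antioxidant enzymes (0.29, 0.0281) were called higher there too. Detoxification targets (-0.28, 0.013) and redox targets (-0.37, 0.046) were called lower. The estimated correlation was not run from 24 h. In all, 365 probe sets (312 genes) differed at 72 h, 154 higher and 211 lower, against 30 from 24 h, 13 of them shared. At any time 359 (304 genes) differed, against 67 from 24 h. The count at 72 h was 113 and 154 without wild type 0 h replicate 1a and 1b, 59 without mutant 0 h replicate 1b, 221 without either mutant 24 h replicate and 209 without either wild type 48 h replicate. It was 231 without either mutant 48 h replicate, 191 and 124 without wild type 72 h replicate 1a and 1b, 142 and 149 without mutant 72 h replicate 1a and 1b. It was 56 on the arrays of the groups compared alone. The count at any time was 132 and 171 without wild type 0 h replicate 1a and 1b, 75 without mutant 0 h replicate 1b and 80 without wild type 24 h replicate 1b. It was 205 and 180 without mutant 24 h replicate 1a and 1b, 191 and 188 without wild type 48 h replicate 1a and 1b and 193 and 169 without mutant 48 h replicate 1a and 1b. It was 231 without wild type 72 h replicate 1b and 220 and 208 without mutant 72 h replicate 1a and 1b.

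Across the 26833 probe sets, the changes of both genotypes were correlated, with Pearson r of 0.425 at 24 h, 0.502 at 48 h and 0.540 at 72 h, and Spearman rho of 0.421, 0.485 and 0.497. Genes are not independent replicates. Of the 1521 probe sets called in both genotypes at 72 h, 1493 changed in the same direction.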

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

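The tests on squamous genes, on genes near Nfe2l2 and near Xaf1, and the changes counted from 24 h were chosen only after the results were seen. The responses of the genotypes to oxygen differed, by the test of the difference itself, in 365 probe sets at 72 h and in 359 at any time. Against the response of wild type, that of the mutant at 72 h was higher for Mgl2 (log2 3.84, and 1.42 counted from 24 h), Rprml (3.68, and 1.66), Jph2 (3.15, and 0.49), Tgfb1 (3.09, and 0.67), Pigv (2.77, and 1.95), Ighm by its dimmer probe set (2.60, and -0.79), Tinagl1 (2.56, and 1.79) and Ccnd1 (2.54, and 0.40). It was lower for Lce3a (log2 -8.67, and -1.67 counted from 24 h), Defb4 (-6.75, and 0.88), Fam25c (-6.24, and -0.38), Xaf1 (-5.67, and -0.23), Krtdap (-5.50, and -1.36), Sprr3 (-5.44, and -0.61), Lce1a1 (-4.96, and -1.35) and Serpinb3a (-4.52, and -0.17). None of these 16 genes was called from 24 h. It was also lower for S100a8 (log2 -2.33, and -3.31 from 24 h, which is called), Gclc (-1.92, and -1.53) and Gpx2 (-1.45, and -0.79). S100a8, Gclc and Gpx2 lie on array type A, where wild type at 24 h has 1 array.

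Squamous epithelial and skeletal muscle genes were high on the mutant 0 h arrays, which also stood apart in correlation and Gapdh ratio. Loss of Nrf2 acting alike in every mutant sample is argued against by the squamous genes at 24, 48 and 72 h, whose highest median genotype difference was log2 0.043, and by skeletal muscle, whose medians there were -0.21, 0.05 and 0.21. An effect of Nrf2 loss seen only before oxygen stays open, since every mutant array after 0 h was under oxygen. A batch shared with the arrays exported with the same number of decimals stays open, since its test had only 1 sample outside the group, wild type 24 h replicate 1a, whose squamous genes differed from 1b by a median of log2 -0.075 on array types B and C. It also stays open that the mutant 0 h samples may hold tissue lined by squamous epithelium and holding skeletal muscle, since all 27 measured squamous genes had a median of log2 0.63 (10 higher, 0 lower), while a first version without the genes already named gave 0.27 over 21 genes, below its bound of 0.5, and was set aside because it left out called genes. The 27 include genes already named for large changes, so their median and count are no independent test. Of the 27, 14 lie above the filter on other arrays too and 0 are in another list, bright ones on these arrays included Lce3a (42700 to 52550, against at most 327.7 elsewhere), Krtdap (15830, against 479.8), Defb4 (13710 to 15170, against 180.8) and Krt4 (10920, against 1199), and Sprr1b (19390, against a median of 14310), Krt14 (log2 0.05), Krt6a (0.08) and Trp63 (-0.04) were not called.

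Genes near Nfe2l2 differed between genotypes more often than others. Among the 150 genes on each side of Nfe2l2 on chromosome 2, 9 of 136 tested were called at 24 to 72 h, against 248 of 12505 elsewhere. Lost activation by NRF2 of every called neighbour is argued against by the 4 that are higher in the mutant, Scn7a (log2 0.75), Hat1 (1.13), Scn3a (0.86) and Dcaf17 (0.87). A candidate explanation is a chromosome segment around the mutated gene from another strain (one-sided Fisher's exact test, p = 0.00183, and 0.00125 to 0.0604 over 5 window sizes), which would include Cwc22 (chromosome 2, 77881159 to 77946356). For the lower neighbours, Cwc22, Itga4 (log2 -1.25), Fam171b (-1.35), Aplnr (-0.64) and Lypd6b (-0.58), loss of activation by NRF2 was not tested gene by gene and stays open.

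Xaf1 (chromosome 11, 72301461 to 72313733) had an intensity of 87.0 to 92.3 on the 2 wild type 0 h arrays, 3398 to 10000 on the 6 wild type oxygen arrays and 83.4 to 396.8 on the 8 mutant arrays. An interferon response of wild type to oxygen is argued against by the interferon list. Its highest median change was log2 -0.23 on array type A, and -0.18 over all 16 measured members. Wild type animals of 0 h and of oxygen differing in a chromosome segment around Xaf1 is a possible explanation that cannot be told apart from a response of Xaf1 alone, because 2 of 186 genes near it, Alox15 (log2 -0.85) and Mgl2 (-2.25), had such a step but in the opposite direction, against 47 of 12455 elsewhere with a step in either direction (one-sided Fisher's exact test, p = 0.162, and 0.0035 to 0.193 over 5 window sizes). Over all of chromosome 11, 11 of 1069 other genes had a step in either direction, against 38 of 11572 elsewhere (one-sided Fisher's exact test, p = 0.00219), and the bound for the nearer genes was changed after its p was seen, so that the explanation is neither excluded nor established. A response to oxygen that needs Nrf2 is the biological explanation that the design gives, and stays open too, since the called difference in response (log2 -5.67 ± 0.53, adjusted p = 0.000384) is what both would give.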

How the results depend on the processing

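The settings on other baselines were chosen only after the data were seen. No gene or list that was called in the main fit or under the setting reversed under any setting fixed in advance. A change of sign with no call in either was not counted as a reversal. Apart from leaving out replicates, those gave for named genes 5732 values on the same side of the threshold, 350 no longer past it and 18 newly past it, and for lists 814, 42 and 12. Leaving out replicates gave 11155, 1056 and 6 for genes and 1632, 14 and 4 for lists.

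A fit with only the arrays of the groups compared, which pools the spread over fewer arrays, called 148 at 0 h, 0 at 24 h (2539 at an unadjusted p under 0.05 in limma), 19 at 48 h and 27 at 72 h for genotype, 49, 584 and 586 for oxygen in wild type, 3764, 2227 and 2717 in the mutant, and 56 for the difference in response at 72 h. The stricter filter, with fewer probe sets tested, called 91 at 24 h and 171 at 48 h for genotype, and 564 at 72 h and 577 at any time for the difference in response. Trend and robust called 91, 172, 586 and 625 for these, and the cause was not tested. Array type A alone, with fewer probe sets, called 170 at 24 h and 1256 at 72 h in wild type and 2995, 2296 and 2680 at 24, 48 and 72 h in the mutant. The correlation between genotypes was 0.385, 0.466 and 0.505 at 24, 48 and 72 h without a filter, 0.488, 0.566 and 0.598 with the stricter one, and 0.475 at 48 h with a floor. Quantile normalization and the replicate block moved no count by more than 1.5 times. The differences of 1a from 1b correlated over 0.1 in 7 of 15 pairs of groups on array type A, 18 of 28 on B and 2 of 28 on C, so that some but not every pair of groups shared them.

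Leaving out each replicate gave 152 to 738 called at 0 h, 5 to 46 at 24 h, 30 to 101 at 48 h, 74 to 231 at 72 h and 106 to 416 in the mean for genotype, 47 to 484, 421 to 1858 and 815 to 2171 at 24, 48 and 72 h in wild type, 2121 to 6492, 1508 to 4750 and 2043 to 5675 in the mutant, and 59 to 416 at 72 h and 75 to 298 at any time for the difference in response. The correlation ranged over 0.305 to 0.442, 0.428 to 0.502 and 0.447 to 0.540 at 24, 48 and 72 h. It had no value where array type A lost the single array of a group.

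Wild type 0 h as the baseline of the mutant called 2745, 1731 and 3461 at 24, 48 and 72 h, and the difference in response from 24 h called 30 at 72 h and 67 at any time. These baselines leave out the mutant 0 h arrays, the second also those of wild type 0 h. Of the results called in the main fit or under the added setting, 25 changed direction. At 24 h against wild type 0 h these were Lce3a 0.83, Fam25c 0.70, Gstm1 -0.10, Tap1 -0.078, Cyp2f2 -0.053, Cd3e -0.93, Jchain 0.14 and Cd79a -0.75. At 48 h they were Fam25c 0.57, Marco -0.026 and Thy1 -0.26, and at 72 h Fam25c 0.079, Sprr3 0.23, Hspa1b 2.37 and the heat shock list 0.40, which was above 0 before and changed only in the direction of its test. From 24 h they were Ighm -0.79, Defb4 0.88, Perp 0.0044, Hspa1b 0.72, Hspe1 0.37, Acta1 0.71, Tnnc2 0.83, the heat shock list 0.052 and the skeletal muscle list 0.091. In the mean over 24, 48 and 72 h it was the skeletal muscle list at 0.021, where again only the test changed direction. Dim probe sets near the filter, such as the lower probe sets of Eln and Ighm, have changes that depend on the value added before the log2.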

Other observations

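The splits of the samples and the count of genes that changed like Xaf1 were chosen only after the results were seen. Some genes of the gas-exchange and airway epithelium changed under oxygen. Against 0 h of the same genotype, none of their lists held a call with an estimated correlation at 72 h. In wild type at 72 h, 1 of 10 alveolar type 2, 2 of 10 alveolar type 1, 1 of 7 club and 2 of 9 ciliated genes were lower and 0 higher. In the mutant, counted from its 0 h arrays, which stood apart, 1, 2, 2 and 3 were lower, and Aqp5 of alveolar type 1 (log2 1.26) and Cyp4b1 of club cells (log2 0.70) were higher. Scgb3a2, a secretory protein of club cells, fell in wild type (log2 -1.18 ± 0.21, adjusted p = 0.00563) and in the mutant (log2 -1.65 ± 0.21, adjusted p = 0.00026) at 72 h. The surfactant protein Sftpa1 fell in wild type (log2 -1.15 ± 0.24, adjusted p = 0.0112). Pdpn, a membrane protein of alveolar type 1 cells, fell in wild type (log2 -0.92 ± 0.21) and in the mutant (log2 -1.30 ± 0.26). Hopx, a transcription cofactor of alveolar type 1 cells, fell in the mutant (log2 -1.83 ± 0.25, adjusted p = 0.000655) and not in wild type (log2 -0.26, adjusted p = 0.523), and the difference in response was called (log2 -1.57 ± 0.32, adjusted p = 0.048). Against wild type 0 h, the mutant at 72 h gave Hopx at log2 -1.28 (adjusted p = 0.00269), Pdpn at -1.28 and Scgb3a2 at -1.11, and from 24 h the difference in response of Hopx was not called (log2 -0.38, adjusted p = 0.864). Against wild type 0 h the alveolar type 1 list on array type A was lower (median log2 -1.28, adjusted p = 0.00269). Alveolar type 2 (adjusted p = 0.582) and club cells (0.612) were not called there. These list tests used the preset correlation only. The ciliary genes Mlf1 (log2 -1.29 ± 0.33) and Ccdc39 (log2 -0.66 ± 0.17) fell in wild type.

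Antioxidant enzymes outside the NRF2 lists went both ways at 72 h. In wild type the mitochondrial Sod2 rose (log2 0.91 ± 0.17), while the peroxiredoxins Prdx2 (log2 -1.02 ± 0.17) and Prdx4 (log2 -1.10 ± 0.20) fell. Sod3, the extracellular superoxide dismutase, rose in the mutant (log2 2.06 ± 0.26, adjusted p = 0.000422) and was not called in wild type (log2 -0.43, adjusted p = 0.279), with a called difference in response (log2 2.49 ± 0.34, adjusted p = 0.00791). The mutant values count from the 0 h arrays that stood apart, and Sod3 was not called against wild type 0 h (log2 0.60, adjusted p = 0.0956), nor was its difference in response from 24 h (log2 0.77, adjusted p = 0.653). Of the cell cycle genes, the spindle protein Nusap1 (log2 -1.92 ± 0.23) and Stmn1 (log2 -1.11 ± 0.21) fell in wild type.

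For the mean genotype difference with all samples, the count was set against splits that exchanged the genotype of samples within each time. The real split called 415 probe sets, and the highest of the other splits called 181, so that 1 split, the real one, was as large. Splits that mix the genotypes add any true difference to the spread, which lowers their counts. The labels do not say whether 1a and 1b are separate animals, so chance differences between animals are not excluded. The real count was 268 and 260 without wild type 48 h replicate 1a and 1b. It was 106 without wild type 24 h replicate 1b and 157 without mutant 0 h replicate 1b, the replicates that hold the single array of type A of their groups. These 2 counts come from array types B and C alone, while A held 211 of the 415, so that they cannot be compared with the 181.

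Like Xaf1, 68 probe sets of 54 named genes changed in wild type under oxygen and differed between genotypes at 24 to 72 h with the opposite sign. Of them, 40 rose in wild type, as Xaf1 did, and 28 fell. Another 48 probe sets were called in both with the same sign. Both comparisons use the wild type oxygen arrays, with opposite sign, so noise in these favours opposite signs and the 68 are no evidence of a shared step.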
